A study of Rattus norvegicus with 17 samples.

How the data were processed

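RNA from CD4+ T helper cells was measured on 17 Affymetrix whole-transcript rat gene arrays, 1 array per sample. Per the labels, the cells were sorted by flow cytometry from inguinal lymph nodes of female Dark Agouti rats, an inbred strain susceptible to experimental autoimmune encephalomyelitis, a model of multiple sclerosis started here by immunization with myelin oligodendrocyte glycoprotein (MOG). Lymph nodes were taken 7 days after immunization. The rats ate a diet with 0 IU (deprived, 5 arrays), 2 IU (regular, 6 arrays) or 10 IU (supplemented, 6 arrays) of vitamin D from 5 weeks before immunization to the end of the experiment. The amount of feed that these IU refer to is not given in the sources used here. Per the labels' protocols, 250 ng of total RNA per sample was amplified to biotin-labelled sense-strand cDNA.

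The values used are the authors' deposited log2 expression values, 1 per transcript cluster and array. The submitters' processing notes name RMA (robust multi-array average, which corrects background, quantile-normalizes probes and summarizes them) and Partek 6.0. The log base is not written in the table and was read from the range of the values, which is that of RMA log2 output. The probe file, genome build and any filter are not given in the sources used here. No scan date or hybridization batch was at hand, so no batch was tested. The number of arrays limits the precision, and no depth in the sense of read counts exists for arrays.

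The table holds 29214 transcript clusters. A platform annotation paired 15310 of them with 1 gene symbol and 323 with several, and did not list 13581. Of those with 1 symbol, 15279 had an Entrez identifier found in the RefSeq gene table for GRCr8, which was used only to update names, so no coordinates are given. The 14506 distinct genes were each represented by the transcript cluster with the highest mean over all arrays, and the lowest 25% of genes by that mean were left out, which kept 10879 genes with a mean log2 value of at least 5.321. For the 474 tested genes with several clusters, the called clusters disagreed in sign with another cluster in 30 genes for supplemented minus regular diet, 0 for deprived minus regular and 36 for supplemented minus deprived.

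One linear model over the 3 diets was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 14 residual degrees of freedom, 8.19 prior degrees of freedom). The 3 contrasts and a moderated F test over the diets were adjusted with Benjamini-Hochberg over genes at a threshold of 0.05. Changes are differences of mean log2 values with the standard error (SE) of the model, and n gives the arrays per diet. Nothing in the labels says that the replicates of a diet were handled on separate days, so the p-values measure the spread between these samples.

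Before the data were examined, 27 gene lists were fixed: T cell programmes, signalling, metabolism, growth and stress lists, and markers of other cells that a lymph node sort can hold. Lists with at least 5 tested genes entered camera, limma's test of a list against all other genes, with a preset correlation of 0.01 and again with an estimated correlation; fry asked whether a list's genes moved on balance in 1 direction. The red blood cell markers had 4 tested genes and were not tested, which left 26 lists. Members were counted with p-values adjusted over all genes and again adjusted over the list alone. The mean of each list per array was compared with two-sided exact permutation tests, adjusted over the lists, which were added after the data had been seen. Each list median was also set beside 10000 random lists matched on mean expression in 50 intensity bins.

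Genes named in the text follow a rule fixed at the same time: the 12 largest rises and 12 largest falls past the threshold in each contrast, up to 4 members with the smallest p of each list, and fixed genes, among them Vdr, Cyp24a1, Cd4, Foxp3, Tbx21, Gata3, Il17a, Ifng, Il10, Csf2 and Il2. Cyp24a1, Il10 and Csf2 lay below the level filter.

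The spread of an array is the standard deviation (SD) of its log2 values over all transcript clusters. Differences in spread were tested with two-sided exact permutation tests. The correlation of the 2 changes from the regular diet was set beside 1000 random regroupings of the arrays into unchanged groups with a shared control group. The control group of a draw could hold arrays of any diet. The correlation was also recomputed with the 6 regular arrays split into disjoint sets over 10 splits. No 2 arrays held identical values, and the 136 pairwise correlations ran from 0.9773 to 0.9954.

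Alternatives were quantile normalization, median centring, no filter on dim genes, a 50% filter, all transcript clusters, a variance trend with robust moderation, an ordinary linear model, array weights, the replicate number as a block, B cell or macrophage marker means as a covariate, a threshold of 0.1, fits with only the 2 diets compared, and each of the 17 arrays left out in turn. Cyclic loess normalization, array spread as a covariate, and leaving out supplemented replicates 2 and 5 together were added after the arrays had been seen. The procedure was tested on simulated data for 10879 genes, of which 67 were changed by 0.25 log2, 67 by 0.5 and 66 by 1. For supplemented minus regular diet it recovered 34.3% of changes of 0.25 log2, 91% of 0.5 and 100% of 1. For deprived minus regular diet the shares were 34.3%, 95.5% and 100%, and for supplemented minus deprived diet 22.4%, 86.6% and 100%. Of the calls, 5.06%, 3.77% and 4.14% were false. The simulated noise was independent between genes and held no factor shared by an array. Far fewer genes were changed in it than were called in the supplemented comparisons. These shares therefore need not hold for the real arrays.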

Results

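CD4+ T cells from the draining inguinal lymph nodes of MOG-immunized Dark Agouti rats were profiled 7 days after immunization, with 6 arrays from rats on a regular diet (2 IU of vitamin D), 6 from rats on a supplemented diet (10 IU) and 5 from rats on a deprived diet (0 IU). The series was made to ask how dietary vitamin D affects the transcriptome of these cells. Of 10879 genes tested, 4927 differed among the diets in limma's moderated F test.

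The arrays of the supplemented diet had a narrower range of values than the others. Their spread was 1.943 ± 0.0271 (SD, n = 6), against 2.026 ± 0.022 (SD, n = 6) for the regular diet and 2.051 ± 0.0166 (SD, n = 5) for the deprived diet. The supplemented arrays lay below both other diets (exact permutation p = 0.00216, adjusted p = 0.00325, the smallest p that these group sizes allow). The spread of the deprived arrays was higher than that of the regular ones by 0.025, which did not pass (exact permutation p = 0.0693). With 5 and 6 arrays this does not show that the 2 are equal. The first principal component held 51.7% of the variance. Across genes, which are not independent replicates, the change from the regular to the supplemented diet correlated at -0.505 with the mean level of the gene, so that abundant transcripts tended to be lower and dim ones higher. For the deprived diet the same correlation was 0.315.

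**Figure D1:**
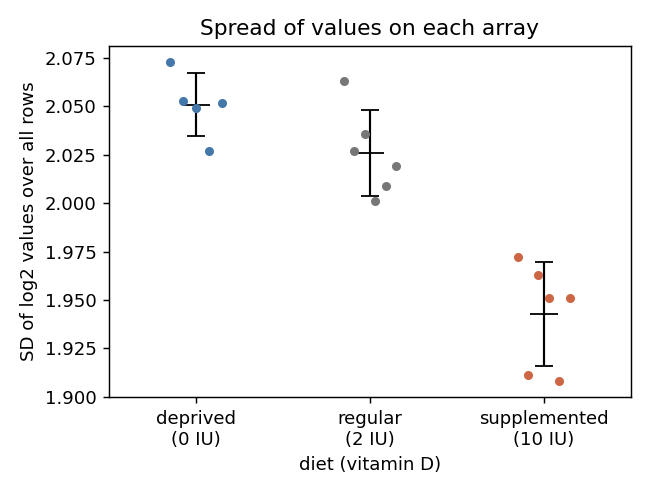
Standard deviation of the log2 values over all transcript clusters of each array (vertical axis, log2 units) by diet, with 1 point per array and bars for the mean ± SD. The 6 supplemented arrays sit between 1.908 and 1.972, below all regular arrays (2.001 to 2.063) and all deprived arrays (2.027 to 2.073).

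Supplementation was compared with the regular diet first. Of 49 cell cycle genes, 29 were lower in T cells of supplemented rats and 20 did not pass (adjusted p = 7.04e-06 for the list, and adjusted p = 0.628 with an estimated correlation). Top2a, the topoisomerase that untangles replicated chromosomes, fell by 1.22 on the log2 scale (SE 0.28, n = 6 and 6, adjusted p = 0.0021). The spindle assembly factor Tpx2 changed by -1.15 (SE 0.21), the G1 kinase Cdk4 by -1.09 (SE 0.17) and the replication clamp Pcna by -0.71 (SE 0.11). Other genes that fell were the respiratory complex I subunits Ndufa9 (-1.14, SE 0.13) and Ndufa2 (-0.83, SE 0.07), the ATP synthase subunit Atp5f1b (-0.74, SE 0.08) and the glycolytic kinase Pgk1 (-0.92, SE 0.12). Cd4 itself, the gene of the sorted surface marker, was lower by -0.59 (SE 0.11, adjusted p = 0.000301). The genes with the largest rises included Prss3bl1 (1.18, SE 0.14), Kctd4 (0.84, SE 0.14) and the complement receptor Cr2, a B cell marker (0.66, SE 0.12). Cr2 was dim, with log2 values of 4.886 to 5.588 on the regular arrays and 5.561 to 6.13 on the supplemented arrays. The lowest mean among the genes tested was 5.321.

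In all, 3661 of 10879 genes changed, 1173 higher and 2488 lower, with 17 of them by more than 2-fold. With each array centred on its median the same number was close (3655), but the split was 312 higher and 3343 lower, since centring moved the median change of all genes to -0.0779. The count was 788 with the mean of the macrophage, monocyte and neutrophil markers as a covariate and 2171 without supplemented replicates 2 and 5, which had the smallest spread. Array means of the macrophage list did not overlap between the 2 diets, so that covariate and diet go together. In limma with array spread as a covariate the count was 0, where 1192 genes had an unadjusted p below 0.05 against 4912 before. With all transcript clusters of the table tested, 6901 changed. Of the 105 named calls, 85 passed after quantile normalization, 85 after cyclic loess, 48 with the macrophage covariate and 0 with the spread covariate.

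Camera called 11 of the 26 lists in this comparison, 8 lower and 3 higher, 0 with an estimated correlation (3 at an unadjusted p below 0.05), and fry called 16. In exact permutation tests of the list means per array, 9 of the 11 passed, but not interferon response genes (p = 0.0519, adjusted p = 0.0844) and B cell markers (p = 0.104, adjusted p = 0.15). Of the 11, 7 had a median outside the 95% range of random lists matched on level, and T cell receptor signalling (-0.29 to -0.0898), cholesterol synthesis (-0.188 to 0.0402), macrophage (0.00974 to 0.143) and stromal lists (-0.0166 to 0.133) lay inside it. Oxidative phosphorylation genes fell broadly: 47 of 55 were lower, 0 higher and 8 did not pass, with 48 lower when adjusted over the list alone (median -0.39, adjusted p = 2.58e-18, and adjusted p = 0.242 with an estimated correlation). Of 67 ribosomal protein genes 57 were lower and 10 did not pass, 60 lower when adjusted over the list alone, for example Rpl11 (-0.71, SE 0.09) and Rpl6 (-0.69, SE 0.07). Their median was -0.28 (adjusted p = 9.73e-18, and adjusted p = 0.294 with an estimated correlation), and after cyclic loess it was -0.0518 and no longer passed (adjusted p = 0.113). Heat shock and unfolded protein genes fell in 20 of 27 members, with 7 not passing and 20 lower when adjusted over the list alone, led by the endoplasmic reticulum chaperone Calr (-0.77, SE 0.10) and the disulfide isomerase Pdia6 (-0.55, SE 0.07). The median of that list was -0.34 (adjusted p = 7.36e-07, and adjusted p = 0.294 with an estimated correlation).

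Cell cycle genes were lower in 29 of 49 members, with 0 higher and 20 not passing. Adjusted over the list alone, 34 were lower and 1 higher. Besides Tpx2 and Pcna, the microtubule regulator Stmn1 (-0.75, SE 0.11) and the replicative helicase subunit Mcm7 (-0.63, SE 0.09) fell. The list median was -0.35 (adjusted p = 7.04e-06, and adjusted p = 0.628 with an estimated correlation), while random lists matched on level had medians of 0.00399 to 0.106. Glycolysis genes fell in 15 of 24 members, 1 rose and 8 did not pass (16 lower and 1 higher when adjusted over the list alone), with a median of -0.23 (adjusted p = 0.000365, and adjusted p = 0.294 with an estimated correlation). Cholesterol synthesis genes, led by the farnesyl diphosphate synthase gene Fdps (-0.83, SE 0.10), fell in 10 of 20 members and did not pass in 10, with 10 lower when adjusted over the list alone. Their median was -0.19 (adjusted p = 0.023, and adjusted p = 0.343 with an estimated correlation).

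**Figure D2:**
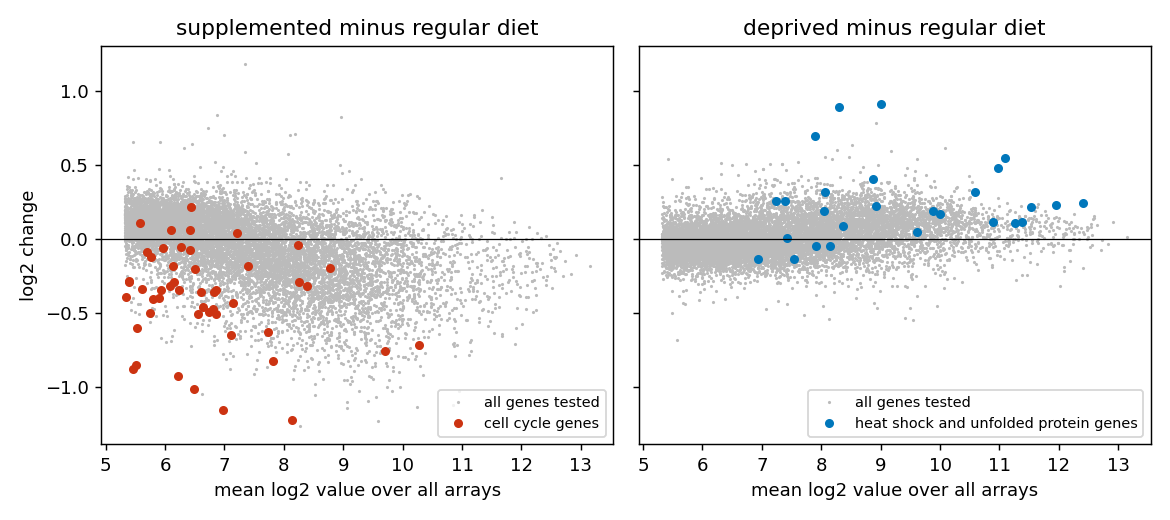
Log2 change (vertical axis) against the mean log2 value over all arrays (horizontal axis) for the 10879 genes tested (grey), with cell cycle genes in red for supplemented minus regular diet (left) and heat shock and unfolded protein genes in blue for deprived minus regular diet (right). On the left, the grey cloud tilts downward at high levels (correlation -0.505) and the cell cycle genes, with a median of -0.35, lie mostly below it at low and middle levels.

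Type I interferon response genes were lower in 17 of 38 members and 21 did not pass, with 17 lower when adjusted over the list alone. The ubiquitin-like modifier Isg15 changed by -0.75 (SE 0.15) and Ifi27 by -0.57 (SE 0.09). The list median was -0.27 (adjusted p = 0.0107, and adjusted p = 0.719 with an estimated correlation), and the call ended after quantile normalization (adjusted p = 0.0567), after cyclic loess (0.0827) and without supplemented replicate 4 (0.072). T cell receptor signalling genes fell in 14 of 36 members, 1 rose and 21 did not pass (15 lower and 1 higher when adjusted over the list alone), among them the receptor subunit Cd3d (-0.35, SE 0.06) and the proximal kinase Lck (-0.43, SE 0.07). Their median of -0.13 passed (adjusted p = 0.013, and adjusted p = 0.719 with an estimated correlation) but turned to 0.023 after quantile normalization and 0.022 after cyclic loess, neither passing.

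Of 6 lists of markers of other cells, camera called 3 as higher beside these falls. B cell markers were higher in 6 of 12 members and 6 did not pass, with 7 higher and 1 lower when adjusted over the list alone. Their median was 0.21 (adjusted p = 0.00798, and adjusted p = 0.343 with an estimated correlation), with Fcrla (0.40, SE 0.09) and Cr2, a dim gene, as examples. Macrophage, monocyte and neutrophil markers rose in 4 of 18 members, among them the adaptor gene Tyrobp (0.32, SE 0.08), 1 fell and 13 did not pass (4 higher and 1 lower when adjusted over the list alone). Their median was 0.10 (adjusted p = 0.0164, and adjusted p = 0.242 with an estimated correlation), and the call ended after quantile normalization (adjusted p = 0.256) and cyclic loess (0.307). Stromal and endothelial markers had 2 members higher, 1 lower and 13 not passing, with 2 higher and 1 lower when adjusted over the list alone (median 0.12, adjusted p = 0.0423, and adjusted p = 0.242 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.341), cyclic loess (0.384), with no filter on dim genes (0.0609), without supplemented replicate 5 (0.0624) and without regular replicate 3 (0.0578). With the dimmest 50% of genes left out, 5 lists were called, and the 3 marker lists no longer passed (B cell adjusted p = 0.433, macrophage 0.124, stromal 0.244). Neither did T cell receptor signalling (0.512), interferon response (0.293) and cholesterol synthesis genes (0.484). With array spread as a covariate 7 lists were called, T cell receptor signalling and JAK-STAT genes as higher (median 0.12, adjusted p = 0.00309, and 0.0837, adjusted p = 0.015) and B cell markers with a median of 0.43 (adjusted p = 0.000119). Oxidative phosphorylation (median -0.127), ribosomal protein (-0.0943), heat shock (-0.197) and cell cycle genes (-0.224) stayed lower in camera with the preset correlation, with smaller medians. The mean of the cell cycle list with this covariate changed by -0.25, with a 95% interval that includes 0 (-0.75 to 0.25). Interferon response (adjusted p = 0.834), glycolysis (0.456), cholesterol synthesis (0.377), macrophage (0.377) and stromal lists (0.967) did not pass there. Without supplemented replicates 2 and 5, T cell receptor signalling genes (adjusted p = 0.136) and stromal markers (0.0922) did not pass.

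Camera did not call the T helper, memory and activation programmes against the other genes. Th1 genes had 0 members higher, 1 lower (the interferon receptor Ifngr1, -0.32, SE 0.07) and 18 not passing, with 0 higher and 1 lower when adjusted over the list alone. Th17 genes had 2 higher, 2 lower and 13 not passing (0 and 1 when adjusted over the list alone), with the transcription factor Stat3 at -0.42 (SE 0.10). Th2 genes had 1 higher, 1 lower and 8 not passing, and 0 and 1 when adjusted over the list alone. Regulatory T cell genes had 1 higher, 1 lower and 18 not passing, and none passed when adjusted over the list alone. Follicular helper genes had 1 higher, 2 lower and 11 not passing (1 and 1 when adjusted over the list alone), and the costimulatory ligand Cd40lg fell by 0.75 (SE 0.11). Naive and central memory genes had 1 higher, 5 lower and 13 not passing (1 and 5 when adjusted over the list alone), including the egress receptor S1pr1 (-0.45, SE 0.09). T cell activation genes had 1 higher, 8 lower and 21 not passing, and 1 and 8 when adjusted over the list alone, with the transcription factor Jun at -1.26 (SE 0.28) in 5 of 6 arrays and the phosphatase Dusp1 at -0.91 (SE 0.19). The adjusted p of these 7 lists ran from 0.31 to 0.919. The array means of naive and central memory genes (exact permutation, adjusted p = 0.0141) and T cell activation genes (adjusted p = 0.03) were lower, by -0.103 and -0.145. Their medians, -0.103 and -0.0168, lay inside the range of random lists matched on level (-0.294 to -0.0281 and -0.145 to 0.0333).

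Vitamin D receptor and known target genes had 2 members higher, 6 lower and 13 not passing (3 and 6 when adjusted over the list alone), and camera did not call the list (adjusted p = 0.853). Its median was 0.0452 and its mean -0.0375, so that the summaries differ in sign. The disulfide isomerase Pdia3 fell by 0.47 (SE 0.07), and the receptor gene Vdr was at 0.14 (SE 0.07, adjusted p = 0.12). Median, mean and test also differed in sign for Th1 genes (-0.00217, -0.0142, tested higher), Th2 genes (0.00373, -0.00737, higher) and CD8 T and NK cell markers (-0.0576, -0.0262, higher). Foxp3, Tbx21, Gata3, Il17a, Ifng and Il2, the lineage factors and cytokines fixed beforehand, did not pass in this comparison or in the others below.

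Further lists that camera did not call against the other genes were JAK-STAT and cytokine signalling genes (1 higher, 8 lower, 26 not passing, and 1 and 7 when adjusted over the list alone), T cell trafficking genes (2, 8 and 18, and 2 and 8 when adjusted over the list alone), apoptosis genes (0, 9 and 19, and 0 and 9 when adjusted over the list alone) and DNA methylation and chromatin enzyme genes (0, 10 and 19, and 0 and 10 when adjusted over the list alone). Their adjusted p was 0.238, 0.526, 0.0738 and 0.0958, and apoptosis genes passed as lower without supplemented replicate 3 (adjusted p = 0.041) or 6 (0.0472). With no filter on dim genes JAK-STAT (adjusted p = 0.0278), apoptosis (0.00878) and DNA methylation genes (0.00878) passed as lower. The array means of these 4 lists were lower in the exact permutation test (adjusted p = 0.0173, 0.0281, 0.0113 and 0.0113), and fry called them too (0.0323, 0.024, 0.00612 and 0.0129), while their medians lay inside the range of random lists matched on level. Named members that fell were the kinase gene Jak1 (-0.31, SE 0.06), which did not pass after quantile normalization or cyclic loess, the deacetylase gene Hdac1 (-0.50, SE 0.09) and the maintenance methyltransferase Dnmt1 (-0.32, SE 0.06). Plasma cell markers had 1 higher, 1 lower and 4 not passing (1 and 2 when adjusted over the list alone), CD8 T and NK cell markers 1, 1 and 8 (0 and 0 when adjusted over the list alone) and dendritic cell markers 1, 1 and 10 (1 and 1 when adjusted over the list alone). Their adjusted p was 0.894, 0.853 and 0.489.

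**Figure D3:**
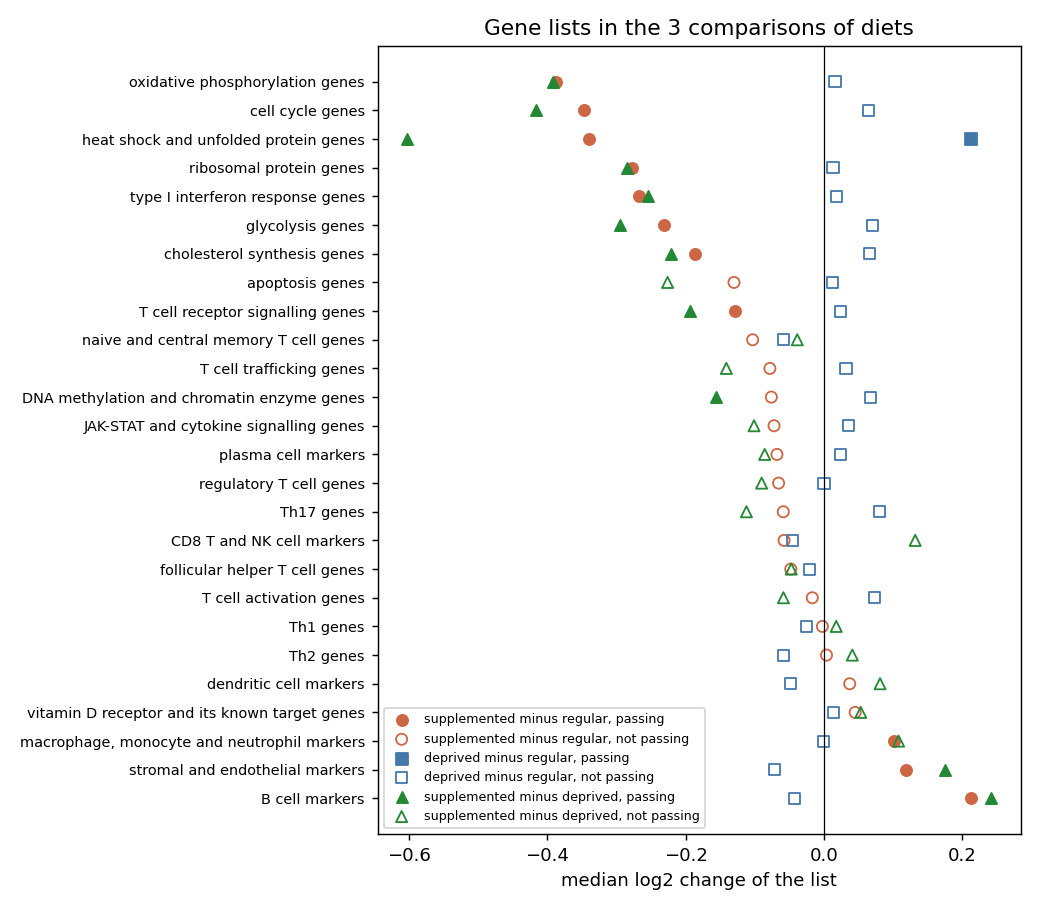
Median log2 change (horizontal axis) of each of the 26 gene lists (vertical axis) in the 3 comparisons of diets, with filled symbols for lists called by camera with the preset correlation. Heat shock and unfolded protein genes are the filled list for deprived minus regular diet, at 0.21, and T cell receptor signalling genes, drawn at -0.13 and -0.19 for the supplemented comparisons, lie above 0 after quantile normalization or cyclic loess.

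Deprivation was then compared with the regular diet. Some heat shock genes rose in T cells of deprived rats, 7 of the 27 tested (adjusted p = 1.52e-09 for the list, and adjusted p = 0.386 with an estimated correlation). The HSP110 gene Hsph1 was higher by 0.91 (SE 0.11, n = 5 and 6, adjusted p = 0.000124), and the HSP40 co-chaperone Dnaja1 by 0.55 (SE 0.07). The co-chaperones Dnajb1 (0.89, SE 0.18) and Dnajb4 (0.69, SE 0.15) rose as well, although neither passed without deprived replicate 4 (adjusted p = 0.0528 and 0.0696), and Dnajb4 also missed the threshold without regular replicate 5 (0.0519) or 6 (0.0711). Both missed it after quantile normalization, Dnajb4 also after cyclic loess and Dnajb1 with the spread covariate. The early activation antigen Cd69 (0.62, SE 0.09), the chemokine receptor Cxcr4 (0.60, SE 0.07), the glucocorticoid-induced gene Tsc22d3 (0.63, SE 0.11) and the stress-induced mTOR inhibitor Ddit4 (0.55, SE 0.08) were higher too. Each of the 28 named calls showed its direction in 5 of 5 deprived arrays. These are the arrays that gave the calls, so this adds no separate support.

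A total of 182 of 10879 genes changed, 162 higher and 20 lower, 0 by more than 2-fold, and 1816 had an unadjusted p below 0.05. The split was 26 higher and 14 lower after quantile normalization (40 genes) and 56 higher and 28 lower after cyclic loess (84 genes). The count was 68 with array spread as a covariate, 889 with array weights, 407 at a threshold of 0.1, 466 with only the 2 diets fitted and 301 without supplemented replicates 2 and 5. Leaving out a single array lowered it to 46, 102, 51, 104 and 33 for deprived replicates 2, 3, 4, 5 and 6, and to 79, 102, 83, 68 and 42 for regular replicates 1, 2, 4, 5 and 6. Of the 28 named calls, 9 passed whichever array was left out: Hsph1, Dnaja1, Cd69, Cxcr4, Tsc22d3, Ddit4, Edrf1, Nck1 and Morc2b.

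Camera called 1 of the 26 lists, and 0 with an estimated correlation (3 at an unadjusted p below 0.05), and fry called 2. Heat shock and unfolded protein genes rose in 7 of 27 members, 0 fell and 20 did not pass, with 13 higher when adjusted over the list alone (median 0.21, adjusted p = 1.52e-09, and adjusted p = 0.386 with an estimated correlation). The mean of the list was higher in 5 of 5 deprived arrays than the regular mean, by 0.247 (exact permutation p = 0.00216, adjusted p = 0.0281). Stromal and endothelial marker means were lower in the same test, by -0.081 (adjusted p = 0.0281), and no other list passed it. The heat shock median and those of 6 lists without a camera call lay outside the range of random lists matched on level: Th17, T cell activation and cell cycle genes above it, and naive and central memory, oxidative phosphorylation and ribosomal protein genes below it. In camera the remaining 25 lists had medians from -0.0715 to 0.0805 and adjusted p of 0.0732 or more. Stromal and endothelial markers, at the lower end, passed without deprived replicate 5 (adjusted p = 0.023) or 6 (0.0465), and cell cycle genes (median 0.0642) passed as higher without deprived replicate 6 (0.00683), which made the count of called lists 2 and 3. Naive and central memory, oxidative phosphorylation and ribosomal protein genes passed as lower after quantile normalization or cyclic loess, which made it 4 in each.

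Few members of those lists passed singly. The Th2 cytokine gene Il13 was lower by -0.41 (SE 0.10, adjusted p = 0.0335), the sole Th2 gene called of 10 (3 lower when adjusted over the list alone), and without any of deprived replicates 2, 4 and 6 or regular replicates 1, 2, 4, 5 and 6 it did not pass (adjusted p from 0.0581 to 0.099), nor after quantile normalization, cyclic loess or with the spread covariate. The ATP synthase subunit Atp5f1e fell by 0.55 (SE 0.11) as 1 of 55 oxidative phosphorylation genes (2 lower when adjusted over the list alone), and not without deprived replicate 6 (adjusted p = 0.0768) or regular replicate 6 (0.0621). Cxcr4 was the 1 trafficking gene of 28 that rose (3 higher and 1 lower when adjusted over the list alone) and Cd69 the 1 activation gene of 30 (1 when adjusted over the list alone). The Th17 chemokine Ccl20 (0.25, SE 0.06), the ectonucleotidase Nt5e of the regulatory list (0.29, SE 0.06), the interleukin 7 receptor Il7r (0.24, SE 0.06) and the apoptosis inhibitor Xiap (0.28, SE 0.07) rose as the 1 call of their lists, Il7r in the naive and the JAK-STAT list. None of these 4 passed without deprived replicate 2 (adjusted p = 0.118, 0.0681, 0.113 and 0.0728), 4, 6 or regular replicate 6, nor after quantile normalization or with the spread covariate. Adjusted over the list alone 6 apoptosis genes were higher and 1 lower. None of the 21 vitamin D receptor and target genes passed, over all genes or adjusted over the list alone, and Vdr was at 0.04 (SE 0.07) and Cd4 at -0.007 (SE 0.11). Median, mean and test differed in sign for Th1 genes (-0.0253, 0.00593, tested lower), oxidative phosphorylation (0.016, -0.0265, lower), ribosomal protein genes (0.0132, -0.00399, lower), plasma cell markers (0.0234, 0.00285, lower) and macrophage, monocyte and neutrophil markers (-0.00115, 0.0207, higher).

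**Figure D4:**
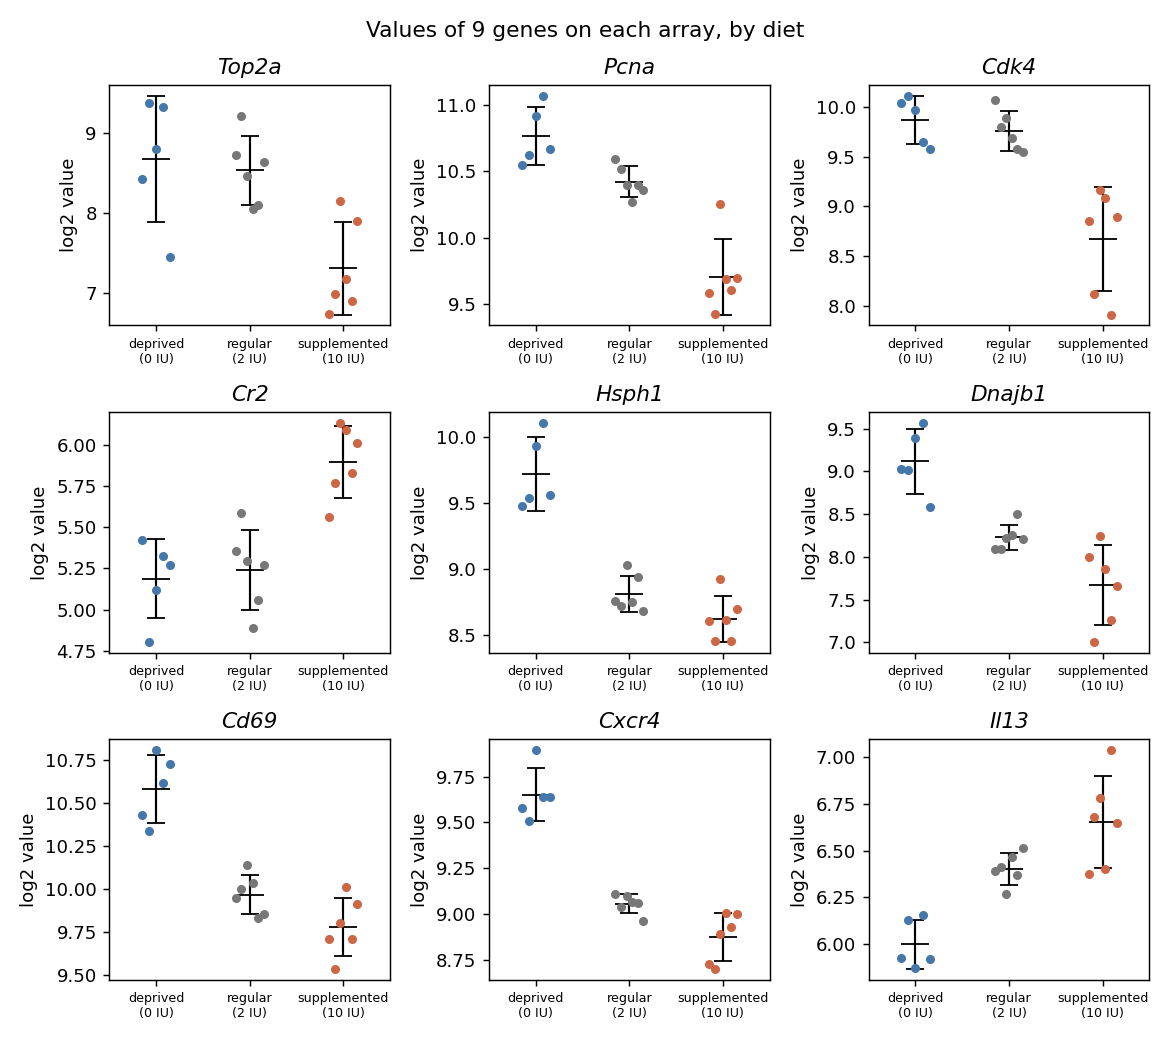
Log2 value (vertical axis) of 9 genes on each array by diet (horizontal axis), with 1 point per array and bars for the mean ± SD. Top2a, Pcna and Cdk4 are lower and Cr2 is higher on the 10 IU diet, Hsph1, Dnajb1, Cd69 and Cxcr4 are higher on the 0 IU diet, and Il13 is lowest on the 0 IU diet.

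Without array spread as a covariate, the supplemented and deprived diets, the ends of the dose range, differed most in number of genes. With that covariate 0 genes passed here, against 68 in deprived minus regular diet. Jun fell by 1.86 (SE 0.30, n = 6 and 5) in supplemented against deprived rats, Dnajb1 by 1.45 (SE 0.18), Hsph1 by 1.10 (SE 0.11), Pgk1 by 1.22 (SE 0.12), Top2a by 1.36 (SE 0.29) and Pcna by 1.06 (SE 0.12). Cxcr4 (-0.78, SE 0.07), Cd69 (-0.81, SE 0.09) and the monocyte chemokine receptor Ccr2 (-1.02, SE 0.19) were lower, and so was Cd4 (-0.58, SE 0.11). Il13 was higher by 0.66 (SE 0.10, adjusted p = 1.21e-05), as were Cr2, a dim gene (0.71, SE 0.12), and the B cell receptor subunit Cd79b (0.42, SE 0.09).

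Of 10879 genes 5132 changed, 2019 higher and 3113 lower, 58 of them by more than 2-fold. With each array centred on its median, which moved the median change of all genes to -0.103, the split was 607 higher and 4177 lower. The count was 2517 with the macrophage, monocyte and neutrophil marker mean as a covariate, 10785 over all transcript clusters and 0 in limma with array spread as a covariate, where 1206 genes had an unadjusted p below 0.05 against 6006 before. Array means of the macrophage list did not overlap between these 2 diets either.

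Camera called 11 lists, 9 lower and 2 higher, 0 of them with an estimated correlation (2 at an unadjusted p below 0.05), and fry called 19. In exact permutation tests of the list means per array, 10 of the 11 passed, but not interferon response genes (adjusted p = 0.0596). Of the 11, 6 had a median outside the 95% range of random lists matched on level, and T cell receptor signalling (-0.367 to -0.157), cholesterol synthesis (-0.234 to 0.0534), ribosomal protein (-0.308 to -0.198), DNA methylation (-0.27 to -0.00573) and stromal lists (-0.0168 to 0.176) lay inside it. A further 6 lists passed that test without a camera call: JAK-STAT (0.00625), trafficking (0.00938), apoptosis (0.00938) and activation genes (0.0216), lower, and macrophage (0.00625) and dendritic cell markers (0.0338), higher. Heat shock and unfolded protein genes fell in 22 of 27 members and 5 did not pass, with 22 lower when adjusted over the list alone (median -0.60, adjusted p = 4.38e-10, and adjusted p = 0.38 with an estimated correlation). Oxidative phosphorylation genes fell in 44 of 55 members and 11 did not pass (46 lower and 1 higher when adjusted over the list alone), with a median of -0.39 (adjusted p = 1.17e-11, and adjusted p = 0.389 with an estimated correlation). Cell cycle genes fell in 33 of 49 members, 1 rose and 15 did not pass (35 lower and 1 higher when adjusted over the list alone), with a median of -0.42 (adjusted p = 0.000106, and adjusted p = 0.513 with an estimated correlation). Glycolysis genes fell in 17 of 24, 1 rose and 6 did not pass (18 lower and 1 higher when adjusted over the list alone), with a median of -0.295 (adjusted p = 0.000223, and adjusted p = 0.389 with an estimated correlation). Cholesterol synthesis genes fell in 11 of 20, 2 rose and 7 did not pass (12 lower and 2 higher when adjusted over the list alone), with a median of -0.22 (adjusted p = 0.0211, and adjusted p = 0.41 with an estimated correlation).

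Ribosomal protein genes fell in 56 of 67 members, 1 rose and 10 did not pass (58 lower and 1 higher when adjusted over the list alone). Their median of -0.28 (adjusted p = 1.06e-11, and adjusted p = 0.41 with an estimated correlation) turned to 0.011 after cyclic loess. T cell receptor signalling genes fell in 20 of 36, 2 rose and 14 did not pass (20 lower and 2 higher when adjusted over the list alone), and their median of -0.19 (adjusted p = 0.00996, and adjusted p = 0.553 with an estimated correlation) turned to 0.023 after quantile normalization and 0.038 after cyclic loess. Type I interferon response genes fell in 18 of 38, 3 rose and 17 did not pass (20 lower and 3 higher when adjusted over the list alone). Their median was -0.25 (adjusted p = 0.0218, and adjusted p = 0.653 with an estimated correlation), a call that ended after quantile normalization (0.15), cyclic loess (0.173), without supplemented replicate 4 (0.0803) and without deprived replicate 3 (0.0681). DNA methylation and chromatin enzyme genes fell in 14 of 29 and 15 did not pass (14 lower when adjusted over the list alone). Their median was -0.16 (adjusted p = 0.0219, and adjusted p = 0.513 with an estimated correlation), a call that ended after quantile normalization (0.453), cyclic loess (0.481) and without supplemented replicate 5 (0.0654). With array spread as a covariate 7 lists were called, and T cell receptor signalling (median 0.15, adjusted p = 0.00267), JAK-STAT (0.0965, adjusted p = 0.0354) and naive and central memory genes (0.18, adjusted p = 0.0367) passed as higher, with B cell markers at 0.51 (adjusted p = 0.000585). Heat shock (median -0.344), cell cycle (-0.225) and oxidative phosphorylation genes (-0.0796) stayed lower in camera with the preset correlation, with smaller medians. Glycolysis (adjusted p = 0.579), cholesterol synthesis (0.355), ribosomal protein (0.325), interferon response (0.804) and DNA methylation genes (0.579) did not pass there, nor did stromal markers (0.579). Without supplemented replicates 2 and 5, T cell receptor signalling (adjusted p = 0.0603), interferon response (0.0635) and DNA methylation genes (0.0871) did not pass.

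B cell markers rose in 5 of 12 members, 1 fell and 6 did not pass (6 higher and 1 lower when adjusted over the list alone). Their median of 0.24 (adjusted p = 0.0204, and adjusted p = 0.447 with an estimated correlation) no longer passed after quantile normalization (adjusted p = 0.0868) or cyclic loess (0.0989). Stromal and endothelial markers, such as the lymphatic chemokine Ccl21 (0.43, SE 0.10), rose in 9 of 16, 1 fell and 6 did not pass (10 higher and 1 lower when adjusted over the list alone). Their median was 0.175 (adjusted p = 0.00723, and adjusted p = 0.119 with an estimated correlation), and the call ended after cyclic loess (adjusted p = 0.0556). With the dimmest 50% of genes left out, 5 lists were called, and B cell (adjusted p = 0.142) and stromal markers (0.0902), T cell receptor signalling, interferon response and cholesterol synthesis genes (each 0.416) and DNA methylation genes (0.499) no longer passed. The other 15 lists had medians from -0.226 to 0.132 and adjusted p of 0.0592 or more. Apoptosis genes passed as lower without deprived replicate 6 (adjusted p = 0.0349) or supplemented replicate 3 (0.0412) or 6 (0.043), and macrophage, monocyte and neutrophil markers as higher without deprived replicate 2 (0.0492) or 4 (0.0438) or supplemented replicate 2 (0.0485). With no filter on dim genes apoptosis (adjusted p = 0.00768), JAK-STAT (0.0153) and trafficking genes (0.0343) passed as lower and macrophage markers (0.0353) as higher. Naive and central memory genes, with a median of -0.0385, passed as higher after quantile normalization (0.18, adjusted p = 0.0196) and cyclic loess (0.21, adjusted p = 0.00571). Median, mean and test differed in sign for vitamin D receptor and target genes (0.0533, -0.0463, tested higher), Th1 genes (0.0178, -0.0201, higher) and follicular helper genes (-0.0472, -0.0697, higher).

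The changes from the regular diet on either side of the dose range were also set against each other. Across the 10879 genes they correlated at -0.192 (jackknife SE 0.162 over the 17 arrays). Unchanged groups with a shared control group gave a median of 0.477 (95% of 1000 draws between 0.119 and 0.724). These groups were random regroupings of the arrays, so their controls were not the 6 regular arrays. The covariance was -0.00569, against 0.00357 for unchanged groups, and with separate control arrays for each change the correlation averaged -0.248 (-0.482 to 0.0264). It moved to -0.0222 after quantile normalization and -0.0186 after cyclic loess. Of the 162 genes higher in deprived rats, 56 were lower in supplemented rats and 27 were higher in both. Independent calls would give 37 and 17.5, as 2488 genes were called lower and 1173 higher in supplemented rats. The 20 genes lower in deprived rats included 5 that were higher in supplemented rats and 5 lower in both (2.16 and 4.57 if independent). Overlaps in the same and in opposite directions all lay above these values, so they do not single out opposite responses. These overlaps were not tested, since both changes share the 6 regular arrays.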

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

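The tests of explanations in this part, the splits of the samples included, were chosen after the results they bear on had been seen.

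A gap between 1 array and the others of its diet, as a share of the range of that diet, was above Dixon's 95% critical value in 38 of 804 sets of arrays (named genes and list means). Chance flags about 1 in 20 groups. On deprived replicate 3, Isg15 (0.856), Pgk1 (0.758), Nrp1 (0.799), Irf7 (0.739) and type I interferon response genes (0.744) stood above and Dppa3 (0.744) stood below. On regular replicate 1, Dusp10 (0.749), Selplg (0.851), Tnfsf10 (0.936), Bcl6 (0.773) and JAK-STAT and cytokine signalling genes (0.664) stood above and Csf3r (0.659) stood below. On deprived replicate 6, Xiap (0.757) stood above and Stat3 (0.819) and Ccl21 (0.762) stood below. On regular replicate 4, Il9 (0.639) stood above. On supplemented replicate 3, Pcna (0.672), Rgs2 (0.661) and Th17 genes (0.663) stood above and Crlf2 (0.692) stood below. On deprived replicate 4, Birc2 (0.714) stood above and Hdac1 (0.839) and Sdc1 (0.713) stood below. On supplemented replicate 2, Vdr (0.769) stood above. On deprived replicate 2, Pdgfrb (0.802) stood above and Ifng (0.797), Il24 (0.834) and Bcl10 (0.821) stood below. On deprived replicate 5, Nfkbia (0.774), Spp1 (0.77) and stromal and endothelial markers (0.846) stood above and Ddit4 (0.778) stood below. On supplemented replicate 5, Zbtb46 (0.672) stood above and Edrf1 (0.793) stood below. On regular replicate 2, Hist3h2ba (0.79) stood above. On supplemented replicate 1, Il24 (0.787) stood below. On supplemented replicate 6, Nr4a3 (0.738) stood above. On supplemented replicate 4, Mcm2 (0.642) stood below. Regular replicate 1 and deprived replicate 3 held 6 of these each. Transcript clusters that the platform annotation did not list were used only where all clusters were tested, and some passed there in limma. Of 13581, 1760 were higher and 1109 lower in supplemented than regular arrays, and 87 higher and 37 lower in deprived than regular arrays. Among the genes tested, 1173 were higher and 2488 lower in supplemented arrays. Array spread was not a covariate in that fit, so a response to diet cannot be read from these clusters.

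The broad change of the supplemented arrays went with their narrower spread. Compression that depends on the mean level alone is argued against as the whole cause, since 2690 genes were called after cyclic loess had brought the correlation of change with level to -0.0836, of which 2054 were among the 3661 called before, in the same direction. An array factor that also varies among arrays of the same diet stays open. The slope of each gene on array spread within the regular diet correlated across genes at -0.515 with the change (11 of 720 orders of the arrays as low, exact one-sided p = 0.0153). Within the supplemented diet the correlation was -0.621 (exact one-sided p = 0.0319) and within the deprived diet -0.155 (exact one-sided p = 0.233). Spread is computed from the same values, so abundant genes tend to have positive slopes on it. The change itself correlated at -0.505 with level. Reordering the arrays breaks that built-in link, so these values cannot decide for such a factor. A response to the diet stays open, and no test here separated it from such a factor. A lower share of CD4+ T cells in the sort stays open, as B cell and CD8 T and NK cell markers moved apart by 0.216 with an exact permutation p = 0.0563.

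Cell cycle genes were lower in supplemented than regular arrays, with a median of -0.347 (adjusted p = 0.628 with an estimated correlation). Compression by level is argued against, since lists matched on level had medians of 0.00399 to 0.106. Fewer dividing B cells stay open: the B cell marker mean was higher by 0.189 with an exact permutation p = 0.104, it rose and fell with the cell cycle mean within diets (correlation 0.764), and it does not measure how many B cells divide. Array spread was tested first in camera with spread as a covariate (median -0.224, adjusted p = 0.00121 with the preset correlation) and, after that had been seen, by the list mean with the same covariate, which changed by -0.25 (95% interval -0.75 to 0.25, against -0.395 without it). An array factor and less cell division on the supplemented diet cannot be told apart, because spread and diet go together.

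Heat shock genes were higher in deprived than regular arrays. The same 2 tests of array spread gave an adjusted p of 5.09e-07 in camera with the preset correlation (without the covariate, adjusted p = 0.386 with an estimated correlation) and, in the version chosen after that was seen, a change of the list mean of 0.206 (95% interval 0.0677 to 0.344), which argues against spread as the whole cause. Stress of the deprived samples during sorting was tested with 12 immediate early genes, of which 6 were higher and 6 lower and 0 passed in limma (median 0.0215, from -0.123 to 0.6), so it stays open. Higher heat shock transcripts in the rats themselves is a hypothesis that these data cannot separate from it.

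Of 100 splits of the samples, the real one included, 1 gave as many genes as the real split in supplemented minus regular diet (3661, highest other 2465), 1 in deprived minus regular diet (182, highest other 91), 1 in supplemented minus deprived diet (5132, highest other 1) and 1 in the F test (4927, highest other 2129). That is the smallest share that 100 splits can give, so random splits seldom reach these counts. In the supplemented comparisons diet and array spread go together, so the splits cannot separate the diet from an array factor. For the counts of lists chance is not excluded: 7 splits reached the 11 lists of supplemented minus regular diet (highest other 13), 94 the 1 list of deprived minus regular diet (highest other 13) and 15 the 11 lists of supplemented minus deprived diet (highest other 14). Splits with 13 lists against a real count of 1 point to a structure of the samples or to correlation between genes, which the preset correlation of 0.01 understates, and the 2 were not separated.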

How the results depend on the processing

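Cyclic loess, array spread as a covariate and leaving out supplemented replicates 2 and 5 together were added after seeing the data, and the other alternatives were planned. The cause was not tested for any of the differences below, except where fewer genes or arrays entered the fit.

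Over all alternatives, named genes kept their side of the threshold in 11361 values, lost it in 800, passed newly in 170 and reversed with a call in at least 1 of the fits in 50. For lists, with the direction taken from camera, these were 1835, 70, 28 and 14. Of the values that kept their side, 99 of genes and 94 of lists (medians) had the other sign, none of them passing in either fit. The count of genes in deprived minus regular diet, 182, became 40 after quantile normalization, 84 after cyclic loess, 68 with the spread covariate, 889 with array weights, 407 at a threshold of 0.1, 466 with only the 2 diets fitted and 301 without supplemented replicates 2 and 5. For supplemented minus regular diet 3661 became 6901 over all transcript clusters, 788 with the macrophage, monocyte and neutrophil covariate, 2171 without supplemented replicates 2 and 5, and 0 with the spread covariate in limma (1192 at an unadjusted p below 0.05). For supplemented minus deprived diet 5132 became 10785, 2517 and, with the spread covariate, 0 (1206 at an unadjusted p below 0.05), and 4927 in the F test became 10011, 2080 and 72. Called lists in supplemented minus regular diet (11) became 7 after quantile normalization, 6 after cyclic loess, 5 with the dimmest 50% left out, 7 with the spread covariate and 0 with an estimated correlation in camera. In deprived minus regular diet 1 list became 4, 4, 2 with no filter, 4 with the spread covariate and 0 with an estimated correlation, and in supplemented minus deprived diet 11 became 6 after cyclic loess, 5 with the dimmest 50% left out, 7 with the spread covariate and 0 with an estimated correlation. The correlation of the 2 changes moved from -0.192 to -0.0222 after quantile normalization and -0.0186 after cyclic loess.

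With each array left out in turn, the counts of genes ran from 2936 to 4035 (supplemented minus regular), 33 to 244 (deprived minus regular), 4451 to 5444 (supplemented minus deprived) and 4165 to 5191 (F test), called lists from 10 to 12, 1 to 3 and 10 to 12, and the correlation from -0.261 to -0.109. Of the named calls, 90 of 105, 9 of 28 and 104 of 115 passed in all 17 fits.

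Lists whose direction in camera reversed, with their medians, were T cell receptor signalling in supplemented minus regular diet (0.0228 quantile, 0.0223 loess, 0.12 spread covariate) and supplemented minus deprived diet (0.0232, 0.0379, 0.153), and naive and central memory genes in the latter (0.181, 0.205, 0.181). Ribosomal protein genes reversed there after loess (0.0108), and interferon response (0.00339) and DNA methylation genes (0.0647) with the spread covariate, which also reversed JAK-STAT genes (0.0837 against the regular and 0.0965 against the deprived diet). Medians of lists that passed in 1 of the fits also changed sign where camera's direction did not. With the spread covariate these were interferon response (0.03) and stromal markers (-0.0446) in supplemented minus regular diet and stromal markers (-0.0111) in supplemented minus deprived diet. In deprived minus regular diet they were oxidative phosphorylation (-0.0592 quantile, -0.0543 loess, -0.0759 spread covariate) and ribosomal protein genes (-0.027, -0.0509, -0.0414). The single genes below lost their call and had the other sign, and none of the values given for them passed. With the spread covariate the lowest adjusted p in limma was 0.541 (Dusp10, supplemented minus regular) and 0.476 (Il6r, supplemented minus deprived). Genes that reversed in supplemented minus deprived diet were Il7r 0.0073 and Ctss 0.0365 after quantile normalization, and Il7r 0.0602 and Ctss 0.0179 after cyclic loess. The spread covariate reversed 20 named genes in supplemented minus regular diet (Ccdc107 0.249, Dusp10 0.275, Txnip 0.0112, Cyp27b1 -0.0127, Ifngr1 0.0383, Stat3 0.000583, Il9 -0.0366, Il6r 0.193, Cd81 0.0151, Il13 -0.102, Angptl2 -0.0517, Jak2 0.0189, Selplg 0.0499, Gpi 0.0425, Pkm 0.0243, Nsdhl 0.116, Sdc1 -0.07, Pecam1 0.0642, Col1a1 -0.0702, Bgn -0.0497) and 26 in supplemented minus deprived diet (Ube2w -0.0623, RT1-M1-2 -0.196, Fam25a -0.101, Ccdc107 0.238, Cdk4 0.202, Spp1 -0.0517, Stat4 0.0313, Il18r1 0.0945, Stat3 0.0366, Ccr6 0.0122, Cd81 0.225, Angptl2 -0.0932, Pdcd1 -0.00609, Il6r 0.316, Rig1 0.000323, Pkm 0.123, Gpi 0.254, Sdc1 -0.193, Ncr1 -0.0105, Ctss 0.0875, Marco -0.0345, Csf3r -0.16, Bgn -0.00866, Pdpn -0.00478, Cdh5 -0.0793, Cd4 0.183).

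The replicate numbers are not explained in the labels. With the number as a block the counts were 3625, 145 and 5332, and 5032 in the F test, no list changed its call, and 11 named genes weakened and 5 strengthened. As a hint from the data, 0 of 6 supplemented and 0 of 5 deprived arrays correlated best with the regular array of their own number. Same-number correlations with regular arrays ran from -0.119 to 0.133 for supplemented and from -0.207 to 0.0766 for deprived arrays. Between supplemented and deprived arrays they ran from -0.114 to 0.195. By level, 25% of genes were left out as dim, and a limit from background on the other dim genes was not tested. Over genes of all tested levels, a change of 0.25 log2 was recovered in 22.4% to 34.3% of simulated cases.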

Other observations

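The gene families in this part were chosen after the data had been seen, and none passed with an estimated correlation (lowest adjusted p = 0.0957).

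In T cells of supplemented rats, several of 15 gene families were lower than on the regular diet. Proteasome subunit genes had a median change of -0.397 (39 of 46 lower), translation initiation factor genes -0.316 (32 of 44), mitochondrial ribosomal protein genes -0.261 (45 of 68), aminoacyl-tRNA synthetase genes -0.288 (16 of 30 lower, 1 higher) and the CCT chaperonin genes, which fold actin and tubulin, -0.473 (7 of 8). Histone genes were at -0.236 (16 of 29 lower, 1 higher). Olfactory receptor genes, which lie near the floor of the arrays (mean level 5.88), were at 0.147 (36 of 152 higher) and keratin genes at 0.164 (9 of 28 higher). After cyclic loess the medians were -0.259, -0.158, -0.233, -0.179, -0.289, -0.178, 0.0433 and 0.0807, with no change of sign. Of the other families, spliceosomal genes were at -0.216 (11 of 20 lower), GTPase of immunity genes at -0.22 (4 of 7 lower, -0.0228 after cyclic loess), solute carrier genes at 0.0713 (35 higher and 19 lower of 237), MHC genes at -0.059 (5 higher and 10 lower of 32) and Rab genes at -0.0572 (5 higher and 16 lower of 53). E2 ubiquitin-conjugating genes were at -0.0151 (2 higher and 7 lower of 27), turning to 0.0176 after cyclic loess, and C2H2 zinc finger genes at 0.0116 (12 higher and 16 lower of 139), turning to -0.0158. In deprived rats the CCT chaperonin genes were at 0.212 (2 of 8 higher, 0.144 after cyclic loess), translation initiation factor genes at 0.0703 (0.0221 after cyclic loess), keratin genes at -0.109 (-0.0762), histone genes at -0.0461 (-0.0717) and olfactory receptor genes at -0.03 (-0.00209). These 5 families passed in camera with the preset correlation (adjusted p = 4.05e-05, 0.00378, 0.000499, 0.00361 and 0.0379). After cyclic loess the translation initiation factor (adjusted p = 0.525) and olfactory receptor genes (0.965) no longer passed, and mitochondrial ribosomal protein genes passed as lower (0.0099).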
